A study of Mus musculus with 4 samples.

How the data were processed

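Mouse embryonic stem cells of the J1 line (129S4/SvJae), grown without feeder cells on gelatin in serum with leukaemia inhibitory factor, were infected with short hairpins against eIF4A3, the RNA helicase of the exon junction complex. Per the labels, 2 hairpins were used, puromycin was given for 3 days, and cells were harvested on day 4.5 after infection. Cycloheximide at 0.1 mg/mL was added for 1 min before lysis. Ribosome protected fragments (RPF) and total RNA were sequenced from 2 biological replicates each, giving 4 libraries, all from knockdown cells. Which hairpin each replicate received, and whether RPF and total RNA libraries with one replicate number come from one lysate, are not given in the sources used here. Libraries of cells without the knockdown were not analysed here.

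The authors' deposited files hold raw read counts per gene, without normalisation, with closing tallies in the form HTSeq writes. Per the labels, reads were 50 bp long, the tools were Bowtie 1.2.3, TopHat2 2.1.1, HTSeq 0.11.2 and edgeR 3.26.8, and the build was mm9. Each RPF library was sequenced in 4 runs; how these were joined, the annotation release, the counted feature and the strand setting are not given in the sources used here. All 4 files list the same 37311 gene identifiers, and the values are whole numbers. Gene counts came to 9434987 and 7615277 in RPF replicates 1 and 2 and to 8969965 and 8218020 in total RNA replicates 1 and 2. A count of 0 allows up to 3 counts, which is 0.318 and 0.394 CPM (counts scaled to the library size) in the RPF libraries and 0.334 and 0.365 CPM in the total RNA libraries. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. The exact intervals given below are for shares of genes and treat genes as independent. Symbols, biotypes, lengths and transcript sequences were taken from GENCODE M21 (GRCm38) by Ensembl identifier without its version. This named 32621 identifiers (87.4%). No coordinates are given, because the counts were made on another build.

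RPF libraries were compared with total RNA libraries in edgeR 4.0.16 (R 4.3.3; limma 3.58.1) with a quasi-likelihood fit of fraction alone. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which kept 13809 genes. Trimmed mean of M-values (TMM) factors were 0.821 and 0.902 for the RPF libraries and 1.14 and 1.18 for the total RNA libraries. The log2 ratio of RPF to total RNA is called the ratio below. Its standard error (SE) was taken as its size over the square root of the F statistic, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Ratios of genes are given ± SE, and levels as TMM-normalised CPM ± SD of 2 libraries, RPF first and total RNA second.

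Gene lists (22, with 694 members) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists were cytosolic ribosomal proteins, other TOP mRNAs, translation initiation factors, integrated stress response uORF mRNAs, ATF4 target genes, pluripotency genes, trophectoderm genes, primitive endoderm genes, mesoderm and neuroectoderm genes, fibroblast (feeder) genes, cell cycle regulators, p53 target genes, exon junction complex and decay factors, SR and splicing regulators, snoRNA host noncoding genes, nuclear noncoding RNAs, replication-dependent histones, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, glycolysis genes, proteasome subunits and chromatin regulators. TOP stands for the 5' terminal oligopyrimidine tract, uORF for an upstream open reading frame. Of the members, 33 had no identifier in the files and 38 were below the count filter, which left 623. Named genes were chosen by rule. The rule took Eif4a3, Ccnb1, Cdk1, Pou5f1, Sox2, Nanog, Klf4, Esrrb, Atf4, Atf5, Ddit3, Ppp1r15a, Malat1, Gas5, Eef1a1, Eef2, Tpt1 and Pabpc1. It also took the 10 highest and the 10 lowest ratios among passing genes with a mean of at least 10 CPM, one direction in all 4 pairings of libraries and a name outside predicted, small RNA and mitochondrial classes; and the extreme members of each list at 10 CPM or more. Tests, lists, the naming rule and the alternative settings were fixed before the data were examined, except those added afterwards. These were a correction for coding share together with exon length, the tests of either correction as the whole cause of a list's ratio, a set of coding genes seen in both fractions, ways of choosing genes without the count filter, and the comparison of replicates with the genes named for it.

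Alternatives were DESeq2 size factors, library size only, TMM without the ribosomal protein, histone, mitochondrial and noncoding lists, no count filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.5, replicate number as a block, a loess (span 0.5) correction for the coding share of the exons, protein-coding genes only, and each library left out in turn. Sequence sharing between genes was measured as the share of 28-base and 50-base stretches of a gene's transcripts that also occur in another gene. Both strands and all annotated genes were included, so genes with overlapping annotation also count as sharing. The measure does not show by itself that reads of a gene were ambiguous. The fit was tested on simulated data with 2 libraries per fraction: of 100 genes with a 2-fold difference it recovered 41%, of 100 with a 4-fold difference 95%, and 6.71% of its calls were false. A simulated list shifted by 0.7 had a camera adjusted p of 6.22e-24, and adjusted p = 0.0207 with an estimated correlation. An unshifted list had 0.51. Simulated genes varied independently, whereas the estimated correlation of the real lists reached 0.94. The simulation therefore does not measure false list calls at the preset correlation.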

Results

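Eif4a3 (ENSMUSG00000025580.9), the gene targeted by the hairpins and the helicase core of the exon junction complex, had 1640 and 1325 counts in RPF replicates 1 and 2 and 1229 and 975 counts in total RNA replicates 1 and 2. Its level was 203 ± 13.3 against 110.5 ± 13.9 CPM (SD, n = 2 libraries per fraction), and its ratio passed as higher (log2 ratio 0.87 ± 0.15 SE, adjusted p = 0.00477). No level from cells without the knockdown stands beside these values, so the depth of the knockdown was not measured. Sequence shared with other genes makes up 41.2% of the 28-base stretches of Eif4a3. The call was not made by glmTreat against a fold of 1.5 (adjusted p = 0.066) or after correction for coding share and exon length (0.23, adjusted p = 0.28). Over all alternatives its adjusted p ran from 8.46e-19 to 0.28.

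The comparison open to the 4 libraries is that of footprints with total RNA in eIF4A3 knockdown cells, which asks how strongly each gene's RNA was occupied by ribosomes relative to other genes. Genes of nuclear-encoded oxidative phosphorylation, glycolysis, the proteasome and histones had more footprints per total RNA than other genes. Nuclear noncoding RNAs had fewer. So did p53 target genes on average, with 7 of 22 lower and a list call that ended after correction for coding share. With an estimated correlation none of these lists was called (lowest adjusted p = 0.456). Nanog and Klf5, which maintain pluripotency, Trp53, the p53 tumour suppressor, and Cdk1, the mitotic kinase, were among the genes with a higher ratio, while Klf4, the translation repressor Eif4ebp2 and the nuclear RNAs Malat1 and Neat1 were among those with a lower one. In all, 2835 of 13809 genes (20.5%) had a higher and 2930 (21.2%) a lower ratio, of which 1299 and 1919 differed at least 2-fold. The split rests on scaling: with library size only, the median of all genes moved from -0.02 to -0.46 and the counts became 1223 higher and 4961 lower (19.8% of calls higher against 49.2%). Without total RNA replicate 2 the counts were 1720 and 1857, more than 1.5 times lower.

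Replicates of one fraction lay closer together than the fractions did. Across genes, which are not independent replicates, Pearson's r was 0.973 between the RPF libraries (Spearman's rho 0.979) and 0.985 between the total RNA libraries (rho 0.988). Between fractions r ran from 0.882 to 0.897. A difference of at least 2-fold separated the RPF libraries at 8.36% of genes and the total RNA libraries at 2.49%. The common biological coefficient of variation was 0.172.

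**Figure D1:**
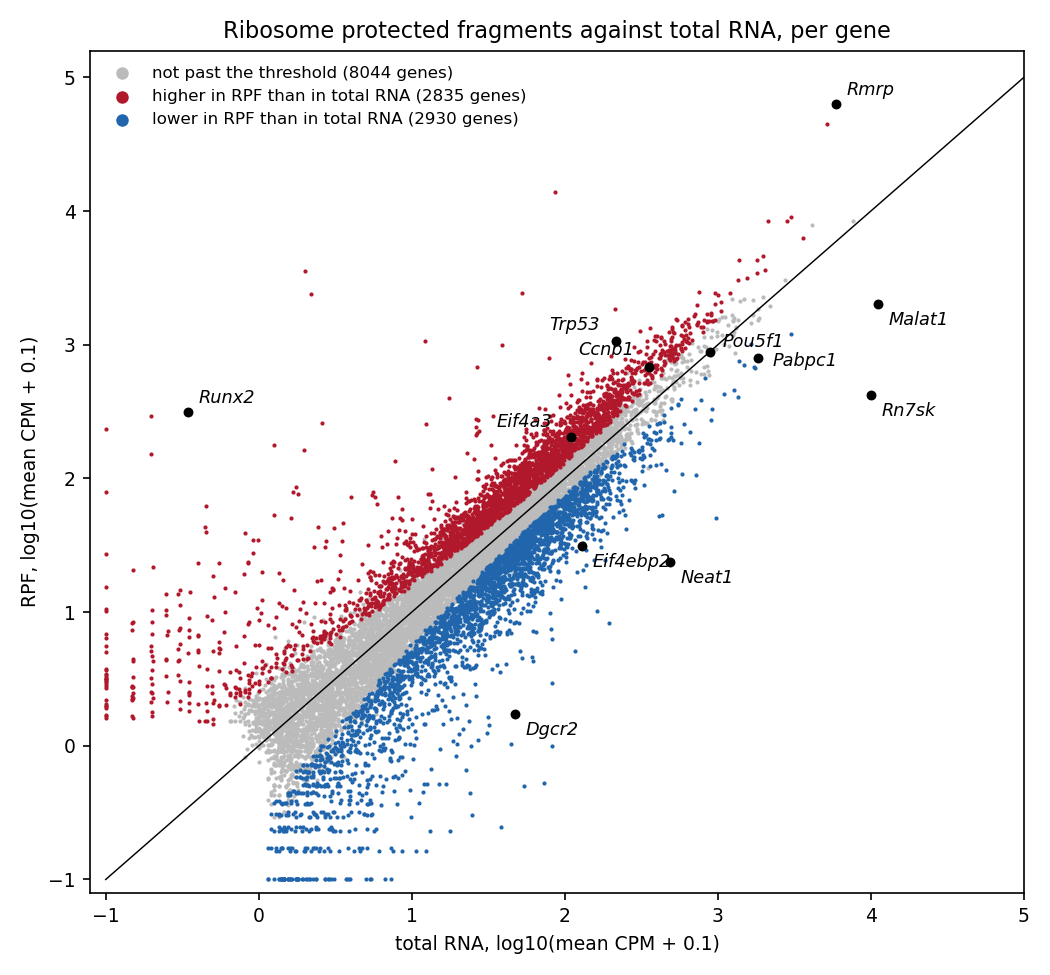
Mean level of each tested gene in total RNA (x axis) and in RPF (y axis), both as log10 of the mean TMM-normalised CPM of 2 libraries plus 0.1, with the line of equal levels. Red points are the 2835 genes with a higher ratio and blue points the 2930 with a lower one; with library size only these counts are 1223 and 4961.

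Protein-coding genes took 84.9 ± 0.167% of RPF gene counts and 92.7 ± 0.745% of total RNA gene counts (SD, n = 2). Small noncoding RNAs made up 8.67 ± 0.143% against 3.21 ± 0.259%, and annotated ribosomal RNA genes 4.61 ± 0.236% against 0.845 ± 0.109%. Rmrp, the RNA of the ribonuclease MRP, held 64.9% and 60.8% of the small noncoding counts in the RPF libraries. Without it the class made up 3.22 ± 0.304% against 2.52 ± 0.157%, and of the 315 tested genes of the class, Rmrp included, 116 were higher and 102 lower. Rmrp, whose 28-base stretches all occur in another gene too, had a level of 63554 ± 6101 against 5969 ± 730.2 CPM (3.41 ± 0.47, adjusted p = 0.00205). Other noncoding RNAs showed the opposite, with 0.578 ± 0.0529% of RPF and 1.97 ± 0.346% of total RNA counts. By class, 2629 of 12655 protein-coding genes were higher and 2443 lower; 136 of 298 other noncoding genes and 85 of 163 pseudogenes were lower, with 13 and 17 higher. The 10 most abundant genes held 15.5% and 14.7% of the counts in the RPF libraries and 6.21% and 6.91% in the total RNA libraries.

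**Figure D2:**
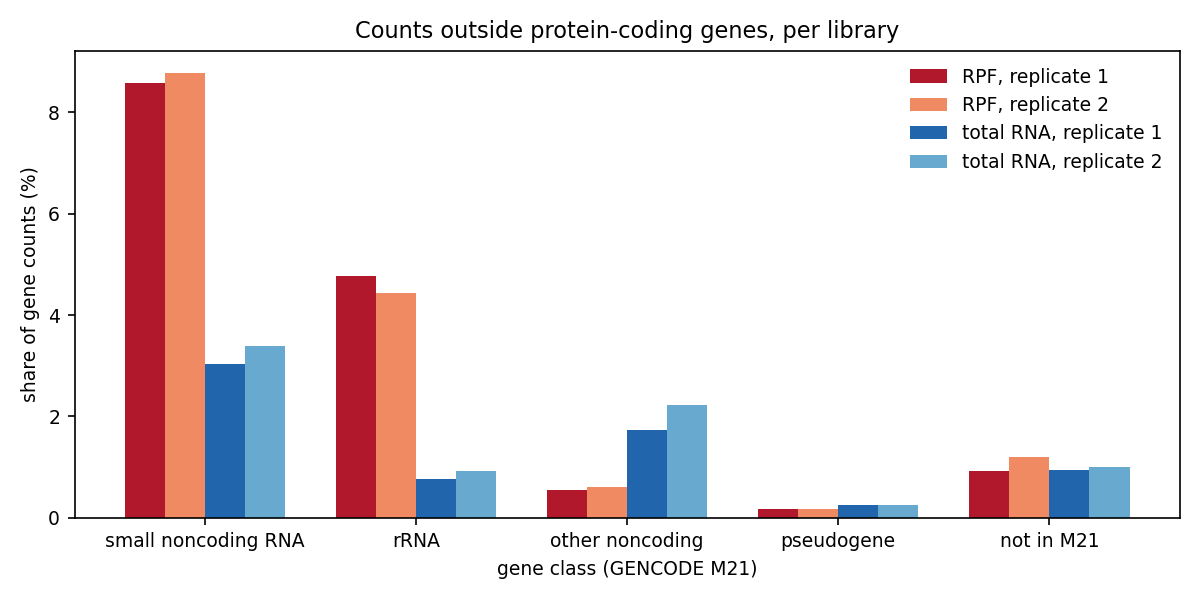
Share of gene counts (percent) taken by small noncoding RNA, ribosomal RNA, other noncoding RNA, pseudogenes and genes absent from the annotation in each of the 4 libraries, 1 bar per library. Small noncoding RNA averages 8.67% in RPF and 3.21% in total RNA, with 3.22% and 2.52% without Rmrp, and other noncoding RNA 0.578% and 1.97%.

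Nuclear-encoded subunits of oxidative phosphorylation had a higher ratio in 69 of 76 members, with 1 lower and 6 not passing (71 higher and 1 lower when adjusted over the list alone). Cox6a1, of cytochrome c oxidase, stood at 1.94 ± 0.15, adjusted p = 0.000489, and Ndufc2, of complex I, at 1.9 ± 0.22. Cox7a2l, a supercomplex assembly factor, was lower (-1.46 ± 0.15, adjusted p = 0.000858), and Cox7c did not pass (-0.28 ± 0.24, adjusted p = 0.384). Their mean exceeded that of other genes by 1.11 (camera adjusted p = 3.1e-20; adjusted p = 0.456 with an estimated correlation). Proteasome subunits were higher in 29 of 31 members (30 higher when adjusted over the list alone). Psmb3 (1.78 ± 0.16) and Psma4 (1.35 ± 0.17), of the core particle, led them, while Psmd8 (0.43 ± 0.14, adjusted p = 0.0429) and Psmd11 (0.27 ± 0.14, adjusted p = 0.165), of the regulatory particle, stood lowest. The mean exceeded that of other genes by 1.13 (camera adjusted p = 1.1e-13; adjusted p = 0.456 with an estimated correlation). Glycolysis genes were higher in 16 of 18 members (18 higher when adjusted over the list alone). They included pyruvate kinase Pkm (1.64 ± 0.36, adjusted p = 0.011), the glucose transporter Slc2a1 (1.52 ± 0.16) and the phosphofructokinases Pfkl (0.71 ± 0.22) and Pfkp (0.67 ± 0.16). Their mean lay 1.22 above that of other genes (camera adjusted p = 1.7e-05; adjusted p = 0.456 with an estimated correlation). Without total RNA replicate 2, Pfkl (adjusted p = 0.245), Pfkp (0.143) and Psmd8 (0.178) did not pass. Psmd8 failed without each of the other libraries too, with an adjusted p of up to 0.355, and its ratio was -0.0043 with library size only.

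**Figure D3:**
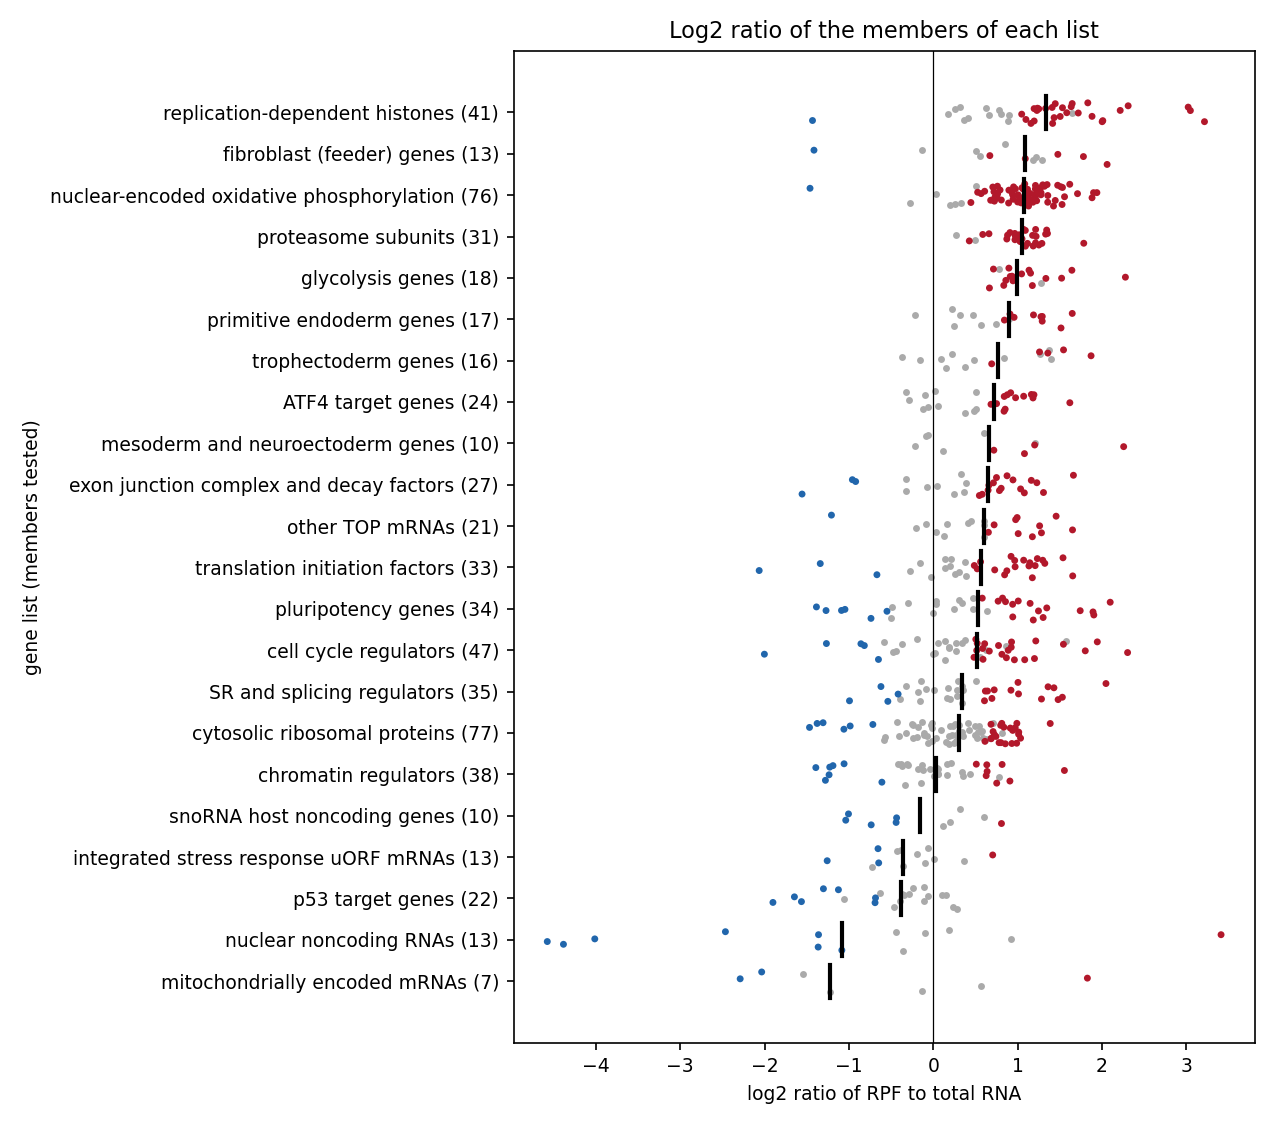
Log2 ratio of RPF to total RNA (x axis) of each tested member of the 22 lists (y axis, ordered by median). Red points are members with a higher ratio, blue points with a lower one and grey points those that did not pass, and black bars are medians. Oxidative phosphorylation and proteasome genes lie mostly to the right of 0; with library size only, the means of ribosomal protein genes (-0.18), cell cycle regulators (-0.02) and splicing regulators (-0.02) fall below 0.

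Ribosomal protein genes were split: 23 of 77 were higher, 6 lower and 48 did not pass (22 higher and 6 lower when adjusted over the list alone), and their mean of 0.26 became -0.18 with library size only (9 higher and 21 lower). Rps16 (1.39 ± 0.26) and Fau (1.04 ± 0.17) were highest, Rps2 (-1.38 ± 0.21) and Rps12 (-1.47 ± 0.27) lowest (adjusted p = 0.00578, 0.00394, 0.00284 and 0.00528). The list's excess over other genes was 0.36 (camera adjusted p = 0.027; adjusted p = 0.785 with an estimated correlation). It lost its call without RPF replicate 1 (adjusted p = 0.689), without total RNA replicate 2 (0.123), with library size only (0.18) and at a mean of at least 10 CPM (0.121). It fell below other genes after correction for coding share and exon length (-0.19, adjusted p = 0.0235). A median of 52.1% of the 28-base stretches of its members occur in another gene, against 1.43% over all tested coding genes.

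The other mRNAs with a TOP motif were higher in 10 of 21 members, lower in 1, and 10 did not pass (11 higher and 1 lower when adjusted over the list alone). The elongation factor subunit Eef1d (1.65 ± 0.21, adjusted p = 0.00158) and the initiation factor subunit Eif3k (1.46 ± 0.18) were higher. Pabpc1, the cytoplasmic poly(A) binding protein, was lower (-1.21 ± 0.22, adjusted p = 0.00587, 798 ± 167 against 1843 ± 169 CPM). Eef1a1 (0.13 ± 0.33, adjusted p = 0.783), Eef2 (0.16 ± 0.28, adjusted p = 0.677), Tpt1 (-0.087 ± 0.24, adjusted p = 0.794) and Eif4b (-0.21 ± 0.23, adjusted p = 0.499) did not pass. The list exceeded other genes by 0.70 (camera adjusted p = 0.00172; adjusted p = 0.593 with an estimated correlation), and its call was lost after correction for coding share and exon length (adjusted p = 0.0993). Translation initiation factors were higher in 19 of 33 members and lower in 3 (20 higher and 3 lower when adjusted over the list alone), with a mean 0.62 above other genes (camera adjusted p = 0.000309; adjusted p = 0.518 with an estimated correlation). Eif5b, which joins the ribosomal subunits (1.65 ± 0.17, adjusted p = 0.00092), and the scaffold Eif3a (1.54 ± 0.18) led the higher ones. Eif4ebp2, a repressor of cap-dependent initiation (-2.06 ± 0.15, adjusted p = 0.000419), and Eif4g2 (-1.34 ± 0.18, adjusted p = 0.00208), a scaffold related to eIF4G, were lower.

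Messages of the integrated stress response with upstream open reading frames were mixed. Atf4, the response's main transcription factor, had a lower ratio (-0.65 ± 0.15, adjusted p = 0.0135, 148 ± 17.8 against 233 ± 12.7 CPM), and so did Ppp1r15b, a phosphatase subunit that acts on eIF2 (-1.26 ± 0.14, adjusted p = 0.00105). Eprs, the glutamyl-prolyl-tRNA synthetase, had a higher one (0.70 ± 0.17, adjusted p = 0.0154). Atf5 (-0.72 ± 0.41, adjusted p = 0.201), Ddit3 (0.013 ± 0.31, adjusted p = 0.977), Ppp1r15a (-0.19 ± 0.15, adjusted p = 0.352) and Cebpb (0.36 ± 0.41, adjusted p = 0.512) did not pass. Of 13 members 1 was higher and 3 were lower, both over all genes and adjusted over the list alone, and the list test was not passed (-0.19; camera adjusted p = 0.255; adjusted p = 0.518 with an estimated correlation). Without total RNA replicate 2 neither Atf4 (adjusted p = 0.0978) nor Eprs (0.111) passed, and Eprs also failed without total RNA replicate 1 (0.13). Over the alternatives the adjusted p of Atf4 ran from 2.84e-11 to 0.344, the highest with glmTreat. Among 24 target genes of ATF4, 13 were higher (14 higher when adjusted over the list alone), such as the amino acid transporter subunit Slc3a2 (1.62 ± 0.20, adjusted p = 0.00155) and the asparaginyl-tRNA synthetase Nars (1.19 ± 0.15). Sesn2 (-0.068 ± 0.14, adjusted p = 0.731) and Mthfd2 (-0.098 ± 0.20, adjusted p = 0.719) did not pass. Their mean exceeded that of other genes by 0.68 (camera adjusted p = 0.0009; adjusted p = 0.456 with an estimated correlation).

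Pluripotency genes were higher in 16 of 34 members, lower in 6, and 12 did not pass (17 higher and 6 lower when adjusted over the list alone). With library size only the counts were 10 higher and 8 lower, and the mean fell from 0.44 to 0.0058. Klf5 (2.1 ± 0.20, adjusted p = 0.000776), the chromatin-associated Utf1 (1.89 ± 0.24) and Nanog (1.01 ± 0.17, adjusted p = 0.00417, 548 ± 22.4 against 272 ± 38.9 CPM) were higher. Klf4 (-1.09 ± 0.22, adjusted p = 0.0084), Tfcp2l1 (-1.27 ± 0.27, adjusted p = 0.01) and the RNA-binding protein Lin28a (-1.38 ± 0.37, adjusted p = 0.0227) were lower. The core factors Pou5f1 (-0.0076 ± 0.21, adjusted p = 0.98), Sox2 (0.25 ± 0.15, adjusted p = 0.218) and Esrrb (0.029 ± 0.17, adjusted p = 0.903) did not pass. The list's mean lay 0.54 above that of other genes (camera adjusted p = 0.00328; adjusted p = 0.456 with an estimated correlation). Lin28a stood at -0.77 without total RNA replicate 1. After correction for coding share, Tfcp2l1 (adjusted p = 0.0785) and Lin28a (0.104) no longer passed; their adjusted p ran from 1.6e-36 to 0.184 and from 2.39e-38 to 0.104 over the alternatives.

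Cell cycle regulators were higher in 22 of 47 members and lower in 5 (23 higher and 6 lower when adjusted over the list alone), with a mean of 0.42 that became -0.02 with library size only (9 higher and 10 lower). Trp53 had the highest ratio among them, at 1072 ± 182 against 217 ± 18.8 CPM (2.3 ± 0.20, adjusted p = 0.000649), followed by the inhibitor Cdkn2a (1.95 ± 0.18). Cdk1 (1.08 ± 0.14, adjusted p = 0.00187) and its partner cyclin B1, Ccnb1 (0.92 ± 0.16, adjusted p = 0.00416, 679 ± 15.6 against 358 ± 7.99 CPM), were higher too. Other genes hold 47.6% of the 28-base stretches of Ccnb1. The transcription factors E2f1 (-1.27 ± 0.16, adjusted p = 0.00167) and E2f2 (-2.0 ± 0.30, adjusted p = 0.00265) were lower. The list exceeded other genes by 0.52 (camera adjusted p = 0.00171; adjusted p = 0.459 with an estimated correlation). Among 22 target genes of p53, 7 were lower, 0 higher and 15 did not pass (6 lower when adjusted over the list alone). Over all tested genes 21.2% were lower. Zmat3, an RNA-binding growth suppressor (-1.9 ± 0.14, adjusted p = 0.000475), and Ccng1, cyclin G1 (-1.65 ± 0.32, adjusted p = 0.00724), were lowest, and Phlda3 (0.28 ± 0.21, adjusted p = 0.335) and Tigar (0.23 ± 0.15, adjusted p = 0.27) highest. The list mean fell by 0.46 below that of other genes (camera adjusted p = 0.0151; adjusted p = 0.542 with an estimated correlation). Its call was lost without RPF replicate 1 (-0.25, adjusted p = 0.0595) and after correction for coding share (-0.27, adjusted p = 0.117), within a range of 0.000729 to 0.117 over the alternatives.

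Magoh (1.31 ± 0.13, adjusted p = 0.000891) and Rbm8a (1.23 ± 0.14), the heterodimer that clamps eIF4A3 on RNA, were higher. The decay factors Smg1, the kinase that acts on UPF1 (-1.56 ± 0.16, adjusted p = 0.00098), and Smg5 (-0.96 ± 0.14) were lower. Of 27 exon junction complex and decay factors 16 were higher, 3 lower and 8 did not pass, and adjusted over the list alone the counts were again 16 and 3. Under library size only they were 7 higher and 6 lower, with a mean of 0.014 in place of 0.44. Their mean exceeded that of other genes by 0.55 (camera adjusted p = 0.0032; adjusted p = 0.456 with an estimated correlation). Among 35 SR proteins and splicing regulators 14 were higher and 4 lower, and as many when adjusted over the list alone, with a mean of 0.41 that became -0.02 with library size only (8 higher and 11 lower). The RNA-binding protein Hnrnpd (1.53 ± 0.21, adjusted p = 0.00218) was higher, and Tia1 (-0.99 ± 0.21, adjusted p = 0.00935) and Son (-0.62 ± 0.16, adjusted p = 0.0186) lower. The list lay 0.51 above other genes (camera adjusted p = 0.00328; adjusted p = 0.518 with an estimated correlation). Son did not pass without total RNA replicate 1 (adjusted p = 0.082) or 2 (0.189). Chromatin regulators went both ways: 8 of 38 were higher and 7 lower, over all genes and adjusted over the list alone. Dnmt3l, a DNA methyltransferase cofactor (1.56 ± 0.32, adjusted p = 0.00882), and the acetyltransferase Kat5 (0.91 ± 0.15) were higher, and the histone methyltransferases Nsd1 (-1.39 ± 0.22, adjusted p = 0.0035) and Kmt2d (-1.28 ± 0.15) lower. The list's median was 0.029, its mean -0.042 and its mean minus that of other genes 0.058, while camera's direction was down (camera adjusted p = 0.752; adjusted p = 0.844 with an estimated correlation).

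Lineage markers were mostly low in total RNA, with a median of 1.98 CPM for trophectoderm, 9.1 CPM for primitive endoderm, 0.508 CPM for mesoderm and neuroectoderm and 1.1 CPM for fibroblast genes, against 156 CPM for pluripotency genes. Primitive endoderm genes were higher in 9 of 17 members (10 higher when adjusted over the list alone). The basement membrane collagens Col4a2 (1.51 ± 0.15, adjusted p = 0.00082) and Col4a1 (1.29 ± 0.18) were among them, while Lrp2 (0.32 ± 0.27, adjusted p = 0.379) and Pdgfra (0.23 ± 0.38, adjusted p = 0.661) did not pass. The list exceeded other genes by 0.93 (camera adjusted p = 0.000958; adjusted p = 0.456 with an estimated correlation). Trophectoderm genes were higher in 5 of 16 members, over all genes and adjusted over the list alone, including Elf3 (1.54 ± 0.24, adjusted p = 0.00305) and keratin Krt18 (1.36 ± 0.20). Tfap2c (0.48 ± 0.17, adjusted p = 0.0561) and Bmp4 (0.38 ± 0.23, adjusted p = 0.225) did not pass. Their excess was 0.88 (camera adjusted p = 0.0151; adjusted p = 0.456 with an estimated correlation). Fibroblast genes, which would mark feeder cells in this feeder-free culture, lay under 1 CPM in total RNA for 11 of 22 genes, with Fn1 most abundant at 679 CPM. They were higher in 5 of 13 and lower in 1 (6 higher and 1 lower when adjusted over the list alone), with an excess of 0.96 (camera adjusted p = 0.0325; adjusted p = 0.503 with an estimated correlation). Timp1 (1.09 ± 0.28, adjusted p = 0.0182) and fibronectin, Fn1 (0.67 ± 0.18, adjusted p = 0.0239), were higher, and Col5a1 (0.56 ± 0.21, adjusted p = 0.0716) and Fbn1 (0.50 ± 0.26, adjusted p = 0.167) did not pass. This list lost its call without RPF replicate 1 (adjusted p = 0.116), at a mean of at least 10 CPM (0.209) and after correction for coding share (0.0838). Fn1 did not pass without any 1 of RPF replicate 1, total RNA replicate 1 or total RNA replicate 2 (adjusted p up to 0.197). Mesoderm and neuroectoderm genes were higher in 4 of 10, as also when adjusted over the list alone, among them the tubulin Tubb3 (1.2 ± 0.18, adjusted p = 0.00272). Ncam1 (1.2 ± 0.44, adjusted p = 0.0642), Dnmt3b (0.60 ± 0.26, adjusted p = 0.106) and Otx2 (0.11 ± 0.22, adjusted p = 0.713) did not pass. That list was not called (0.78; camera adjusted p = 0.0818; adjusted p = 0.518 with an estimated correlation), but passed without RPF replicate 2 (adjusted p = 0.0155) and without total RNA replicate 1 (0.0145). It also passed with library size only (adjusted p = 0.0414), without a count filter (0.0414) and after correction for coding share and exon length (0.0281).

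Replication-dependent histones were higher in 28 of 41 members, lower in 1, and 12 did not pass (29 higher and 1 lower when adjusted over the list alone). The H2A genes Hist1h2ag (3.22 ± 0.39, adjusted p = 0.00149, 242 ± 125 against 26 ± 8.2 CPM) and Hist1h2ac (3.05 ± 0.41) were highest, and stood at 2.57 and 2.26 without RPF replicate 1. Hist1h4k (0.26 ± 0.25, adjusted p = 0.439) and Hist1h2bb (0.18 ± 0.31, adjusted p = 0.678) did not pass. Their mean exceeded that of other genes by 1.42 (camera adjusted p = 3.47e-08; adjusted p = 0.518 with an estimated correlation), and by 0.95 to 1.9 when each library was left out in turn. Over all alternatives in which lists were tested, the excess was as low as 0.61. The summed exon length of these genes is short, with a median of 539 bases per gene against 3383 over all tested coding genes. A median of 56.4% of their 28-base stretches occur in another gene. Of 13 mitochondrially encoded mRNAs, 7 were tested. In total RNA 6 of the 13 lay under 1 CPM, whereas mt-Co1 had 757 CPM, and the cause was not tested. The list result therefore covers only part of these mRNAs. Among the 7 tested, mt-Nd6, the one encoded on the light strand, was higher (1.83 ± 0.48, adjusted p = 0.0219). A further 2 were lower and 4 did not pass, with the same counts adjusted over the list alone. The lowest was mt-Nd1 (-2.29 ± 0.52, adjusted p = 0.0122). Without RPF replicate 1 mt-Nd6 stood at 0.77 and mt-Nd1 at -3.29. The list was not called (-0.59; camera adjusted p = 0.351; adjusted p = 0.785 with an estimated correlation). It passed without RPF replicate 1 (-1.85, adjusted p = 9.74e-07) and without total RNA replicate 2 (-0.95, adjusted p = 0.00401), and was 0.17 without RPF replicate 2 (adjusted p = 0.971). After correction for coding share and exon length it passed as well (-1.45, adjusted p = 0.0358).

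Nuclear noncoding RNAs had the lowest mean ratio of the 22 lists. Of 13 members 7 were lower, 1 was higher and 5 did not pass, over all genes and adjusted over the list alone (-1.1; camera adjusted p = 0.000216; adjusted p = 0.456 with an estimated correlation). The spliceosome-associated Malat1 (-2.46 ± 0.43, adjusted p = 0.00467, 2017 ± 1006 against 11127 ± 2618 CPM), the paraspeckle scaffold Neat1 (-4.38 ± 0.18, adjusted p = 8.06e-05) and Rn7sk, which holds the elongation factor P-TEFb (-4.58 ± 0.31, adjusted p = 0.000355), were lower. Malat1 stood at -3.08 without RPF replicate 2. Rmrp was the higher one, and Rpph1, the RNA of RNase P, did not pass (0.93 ± 0.36, adjusted p = 0.0734). Among 10 noncoding host genes of snoRNAs 5 were lower and 1 higher, also when adjusted over the list alone, and the list was not called (-0.062; camera adjusted p = 0.438; adjusted p = 0.785 with an estimated correlation). Gas5, whose spliced RNA carries a TOP motif, did not pass (0.20 ± 0.16, adjusted p = 0.347), nor did Snhg9 (0.61 ± 0.49, adjusted p = 0.356). Snhg12 was higher (0.81 ± 0.19, adjusted p = 0.0132), and Snhg17 (-1.0 ± 0.15) and Epb41l4aos (-1.04 ± 0.20) lower.

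Among the genes that the naming rule admits, which leaves out predicted, small RNA and mitochondrial names, the highest ratios at a mean of 10 CPM or more belonged to genes with few counts in total RNA. Slc22a19, an organic anion transporter, had 154 and 949 RPF counts and no total RNA counts, at least 262-fold higher against a floor of 3 counts per library, and at least 66-fold from RPF replicate 1 alone. The osteoblast factor Runx2 had 383 and 4001 against 4 and 1 counts (10.22 ± 1.59, adjusted p = 0.00317), and Chadl 578 and 344 against 3 and 4 (7.41 ± 0.37, adjusted p = 0.000116). Prkg2 (6.88 ± 0.48), Kcnj15 (6.77 ± 0.49), Kcnc1 (5.64 ± 0.67), Mapk15 (5.5 ± 0.69), Sema3a (5.22 ± 1.08), Zfp503 (5.07 ± 1.08) and Ggt5 (4.94 ± 0.54) completed the 10, each with at most 15 counts in a total RNA library. With limma-voom, Runx2 (adjusted p = 0.102), Sema3a (0.0803) and Zfp503 (0.0764) did not pass. When each library was left out in turn, the ratio ran from 7.56 to 11.37 for Runx2, 6.16 to 8.5 for Prkg2, 4.69 to 6.22 for Kcnc1, 4.41 to 6.14 for Mapk15, 3.0 to 6.08 for Sema3a, 2.91 to 6.08 for Zfp503 and 4.19 to 5.45 for Ggt5. At the other end of the admitted genes stood Dgcr2, of the DiGeorge region, with 14 and 10 against 469 and 470 counts (-4.83 ± 0.24, adjusted p = 0.000116), followed by Dcdc2c (-4.52 ± 0.32) and Neat1. The others of the 10 lowest were Cd209c (-4.32 ± 0.43), BC018473 (-4.28 ± 0.23), Tmem170b (-4.11 ± 0.52), the noncoding Tug1 (-4.01 ± 0.22), the polycomb protein Cbx6 (-3.86 ± 0.24), Zfp488 (-3.73 ± 0.27) and Srprb, a subunit of the signal recognition particle receptor (-3.68 ± 0.32). With each library left out, Tmem170b ran from -5.46 to -3.45 and Cd209c from -4.92 to -3.88.

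Coding genes with at least 10 CPM in both fractions were ranked as well, a set chosen after the values were seen. Lrrcc1, a centriolar protein (4.68 ± 0.21, adjusted p = 0.000111, 678 ± 110.0 against 26.4 ± 2.19 CPM), Fam124a (4.53 ± 0.39), and Atpaf1, an assembly factor of ATP synthase (3.12 ± 0.36), were among the highest, as were the insulin receptor substrate Irs2 (2.76 ± 0.37) and metallothionein Mt2 (2.51 ± 0.17). Without RPF replicate 2 Fam124a stood at 3.87 and Irs2 at 2.09, and without RPF replicate 1 Atpaf1 at 2.49. Ap4b1 (3.4 ± 1.1, adjusted p = 0.0432), with 85.8% of its 28-base stretches shared, rested on RPF replicate 2, with 215 and 3598 against 260 and 261 counts, and its ratio was 0.10 without it (adjusted p = 0.752, within 7.84e-60 to 0.752 over the alternatives). The kinase Uhmk1 (-3.15 ± 0.25, adjusted p = 0.000489, 15.3 ± 4.59 against 135 ± 26.1 CPM), Coa5, an assembly factor of cytochrome c oxidase (-2.91 ± 0.15), Fam168b (-2.91 ± 0.17), Ccni, cyclin I (-2.6 ± 0.14), and Pank3, a pantothenate kinase (-2.43 ± 0.20), were among the lowest.

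Of the 22 lists, 17 were called by camera at the preset correlation. Among these only nuclear noncoding RNAs and p53 target genes lay below other genes. An excess over other genes was thus shared by lists of unlike function, including lineage markers low in total RNA, and is not particular to 1 pathway. With an estimated correlation camera called 0, with 0 at an unadjusted p under 0.05 (lowest p = 0.0609). The correlation was estimated from the fit of fraction alone, so differences between the replicates enter it. Its results with replicate number as a block are not given here. The test fry asks whether the genes of a list move one way and makes no comparison with other genes. It called 5 (13 at an unadjusted p under 0.05), namely ATF4 targets, exon junction complex and decay factors, nuclear noncoding RNAs, proteasome subunits and trophectoderm genes, each at an adjusted p of 0.0451.

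With library size only, members moved to 7 higher and 0 lower for glycolysis, 51 higher and 2 lower for oxidative phosphorylation, 7 higher and 2 lower for ATF4 targets, 13 higher and 6 lower for initiation factors, 5 higher and 0 lower for primitive endoderm, 1 higher and 1 lower for fibroblast genes, 2 higher and 14 lower for chromatin regulators and 0 higher and 13 lower for p53 targets. Named genes outside the ribosomal protein and histone lists with over 40% of 28-base stretches in another gene were also Mt2 (52.9%), Eef1a1 (76.6%), Tpt1 (44.7%), Dgcr2 (46.7%), Pkm (55.8%), Psma4 (45.6%), Rn7sk (74.3%), Cox7c (46.1%) and Rpph1 (70.5%).

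Some calls of named genes ended under other settings. Calls were lost for 5 named genes with limma-voom, 3 at a mean of at least 10 CPM and 2 with DESeq2. They were lost for 1 without a count filter and 1 with protein-coding genes only. With library size only, Timp1, Fn1, Eprs, Snhg12, Pfkl, Pfkp and Ap4b1 did not pass. Against a fold of 1.5, glmTreat did not call Eif4a3, Ap4b1, Atf4, Timp1, Fn1, Eprs, mt-Nd6, Snhg12, Pfkl, Pfkp, Lin28a, Psmd8, Son and Tia1. After correction for coding share Fn1, Eprs, Pfkl and Ap4b1 did not pass, and after correction for coding share and exon length Fau, Ap4b1, Timp1, Eprs, mt-Nd6, Pfkl, Psmd8, Son and Tia1 did not, besides those named above.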

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

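The correction for coding share was planned, but the tests of either correction as the whole cause of a list's ratio were chosen only after the result was seen. Those of genes with many footprints and almost no total RNA were set before it, except the ways of choosing them without the count filter.

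Reads given to no gene stood apart between fractions, in tallies outside the gene counts and with no control libraries to set them against. Reads in more than one gene made up 6.77 ± 2.56% of RPF records and 0.737 ± 0.0258% of total RNA records (SD, n = 2). Reads outside any gene feature made up 6.3 ± 0.497% of RPF and 24.8 ± 1.98% of total RNA records. Records without a unique alignment made up 21.05% and 20.64% in RPF replicates 1 and 2. In total RNA replicates 1 and 2 they made up 16.64% and 16.55%. How far these tallies bear on the ratios of genes with shared sequence was not tested.

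A group of 112 genes had passing ratios above 4 (log2) and under 1 CPM in total RNA, such as Slc22a19, Runx2 and Chadl. The distance between the RPF libraries had a median of 0.59 (log2) and an upper quartile of 1.03, under the set limit of 2. Of the members, 14 lay at least 4-fold apart. The count filter favours such agreement, since genes with few total RNA counts pass it mainly with counts in both RPF libraries. Over 4 ways of choosing such genes without the filter, the medians ran from 0.763 to 0.925. The upper quartiles ran from 1.48 to 2.77, over 2 in 1. In these choices 12 of 33, 16 of 67, 16 of 63 and 29 of 158 genes lay at least 4-fold apart. The medians argue against a single RPF library as the source of most such genes, and leave it open for the rest. Fragments of small structured RNAs may supply part: 47 members (42%, exact 95% interval 32.7 to 51.7) were small noncoding or ribosomal RNA genes, against 2.35% of all tested genes, and an interval around 50 keeps that share open. Of the 46 protein-coding members, 16 (34.8%, exact 95% interval 21.4 to 50.2) hold a 28-base stretch of such an RNA. Among 12609 other coding genes 38.5% do (Fisher's exact test, two-sided, p = 0.651). This argues against exact shared stretches of that length as the source for all coding members. For the 16 that hold one, shared sequence cannot be told apart from other sources. No biological explanation was tested, since all libraries come from knockdown cells.

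Higher ratios of oxidative phosphorylation, proteasome and glycolysis genes could follow from how much of their exons is coding, since footprints fall on coding sequence. They could also follow from a short summed length of all exons of a gene, called exon length here. Correction for coding share left the excess over other genes at 1.11 ± 0.0647 for oxidative phosphorylation, 0.964 ± 0.0596 for the proteasome and 1.09 ± 0.105 for glycolysis (SE over members), from 1.11, 1.13 and 1.22. Correction for coding share and exon length together left 0.575 ± 0.0697, 0.661 ± 0.06 and 1.03 ± 0.11 (camera adjusted p = 2.62e-05, 2.93e-05 and 6.27e-05). Over most coding genes the fitted trend ran only from -0.53 to 0.285 for coding share, and from -0.63 to 0.65 with exon length. The excesses left after either correction lay above 0 beyond their SE in all of these lists, with members taken as independent. They argue against coding share, alone or with exon length, as the whole cause, as far as the fitted trends measure the effect of these properties. For oxidative phosphorylation genes, a median coding share of 0.496, against 0.493 over all tested coding genes, argues against coding share as the whole cause. A part of the excess of oxidative phosphorylation and proteasome genes went with the trend of coding share and exon length together. No biological explanation was tested, and with an estimated correlation none of these lists was called (adjusted p = 0.456 each).

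The lower ratio of p53 target genes may rest partly on long untranslated regions, since their median coding share was 0.279, against 0.493 over all tested coding genes. Correction for coding share moved the difference from other genes from -0.46 ± 0.134 to -0.27 ± 0.116 (SE over 22 members), and its call ended (adjusted p = 0.117). The difference shrank while its spread stayed similar, so that coding share as the whole cause cannot be told apart from other causes. Correction for coding share and exon length together left -0.33 ± 0.108 (camera adjusted p = 0.0428). This lies within the spread of the value after coding share alone. The uncorrected list had an adjusted p of 0.542 with an estimated correlation. Both trends together as the whole cause can therefore not be told apart from other causes either. No biological explanation was tested.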

How the results depend on the processing

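The correction for coding share together with exon length was chosen only after the data were seen; all other settings were planned. The cause of the changes listed was not tested, unless stated. With library size only, 1223 genes were higher and 4961 lower, since omitting the TMM factors shifts all ratios down by about one amount. Signs turned for Sox2 -0.19, Gas5 -0.24, Eef2 -0.29, Eef1a1 -0.32, Esrrb -0.40, Ddit3 -0.40, Cebpb -0.059, Phlda3 -0.15, Tigar -0.19, Otx2 -0.32, Lrp2 -0.12, Pdgfra -0.21, Psmd11 -0.16, Hist1h4k -0.17, Hist1h2bb -0.27 and Bmp4 -0.042, and Psmd8 (-0.0043). DESeq2 size factors gave Pou5f1 0.018, as did DESeq2 (0.018). Without a count filter Esrrb was -0.012 and Ddit3 -0.027, and at a mean of at least 10 CPM -0.052 and -0.068. Ddit3 was -0.044 with limma-voom and -0.015 with protein-coding genes only. Against a fold of 1.5, glmTreat called 1155 higher and 1549 lower, a stricter hypothesis by construction. Pairing by replicate number is not stated in the labels and rests on 2 pairs (r = 0.41 across genes between the replicate differences of the fractions); with it as a block, 4257 genes were higher and 4365 lower, Ddit3 was -0.018, 16 named genes that did not pass in the reported fit were called, the lists of mitochondrially encoded mRNAs (-0.75, adjusted p = 0.00467) and of mesoderm and neuroectoderm genes (adjusted p = 0.0445) were called, and that of fibroblast genes was not (0.95, adjusted p = 0.0713). Correction for coding share gave Eef2 -0.088, Eef1a1 -0.11, Ddit3 -0.067, Tpt1 0.026, Sesn2 0.030, Cox7c 0.21, Hist1h4k -0.016 and Hist1h2bb -0.045. Correction for coding share and exon length gave Eef2 -0.18, Eef1a1 -0.42, Ddit3 -0.70, Cebpb -0.13, Sesn2 0.034, Hist1h4k -1.06 and Hist1h2bb -0.85, with 0.24 for chromatin regulators and -0.19 for cytosolic ribosomal proteins. With an estimated correlation, camera called 0 lists (0 at an unadjusted p under 0.05; fry called 5). When each library was left out in turn, the remaining single library of that fraction being taken to vary like the others, the higher genes ran from 1720 to 3341 and the lower from 1857 to 3440. Ratios on both sides of 0 were Eef2 -0.19 to 0.47, Eef1a1 -0.20 to 0.42, Esrrb -0.068 to 0.15, Ddit3 -0.49 to 0.42, Pou5f1 -0.16 to 0.16, Tpt1 -0.40 to 0.20, Atf5 -1.22 to 0.022, Cebpb -0.21 to 0.84, Snhg9 -0.46 to 1.22, Sesn2 -0.15 to 0.016, Mthfd2 -0.31 to 0.11, Otx2 -0.085 to 0.33, Cox7c -0.64 to 0.029, Eif4b -0.49 to 0.053, Lrp2 -0.054 to 0.63, Pdgfra -0.21 to 0.86 and Hist1h2bb -0.27 to 0.58, with chromatin regulators -0.062 to 0.20, mitochondrially encoded mRNAs -1.85 to 0.17 and snoRNA host noncoding genes -0.26 to 0.22. None of the single genes listed passed the test in the reported fit, except Psmd8. TMM without the ribosomal protein, histone, mitochondrial and noncoding lists kept the direction and side of the threshold of all 149 named genes and 22 lists. Depth limits low genes: 3 counts are 0.318 to 0.394 CPM.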

Other observations

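The differences between the replicates, and the genes named for them, were looked at only after the data were seen; with 1 library per replicate and fraction they carry no test. The libraries of replicate 2 differed from those of replicate 1 in several gene groups, in both fractions. Target genes of p53 were at higher levels in replicate 2, with a median log2 difference of 0.30 in total RNA and 0.36 in RPF, and 17 of 22 members were higher there in each fraction. Examples, with total RNA first and RPF second, were Ccng1 (0.73 and 0.77), Mdm2 (0.43 and 0.65) and Trp53inp1 (0.38 and 0.54), while Trp53 itself was lower (-0.18 and -0.35). Histone genes were at lower levels in replicate 2 (-0.65 in total RNA and -0.81 in RPF), in all 41 tested members. So were the 7 tested mitochondrially encoded mRNAs (-0.64 in total RNA and -1.75 in RPF). Nuclear-encoded oxidative phosphorylation genes lay lower too (-0.19 in total RNA and -0.20 in RPF), with 8 and 14 of 76 members higher in replicate 2. Ribosomal protein genes were lower as well (-0.17 in total RNA and -0.45 in RPF), with 1 and 3 of 77 members higher in replicate 2. Over all tested genes the medians were 0.0081 and 0.0021, a loose yardstick for abundant genes. Among 10000 random lists matched on expression, the total RNA median of SR and splicing regulators (-0.099) stood at percentile 61. That of ribosomal protein genes stood at percentile 13, and their RPF median at percentile 0. In both fractions oxidative phosphorylation genes, histones and mitochondrially encoded mRNAs stood at percentile 0, and p53 target genes at percentile 100.

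Glycolysis genes were lower in replicate 2 (-0.43 in total RNA and -0.37 in RPF), with 4 of 18 members higher. Lactate dehydrogenase Ldha (-1.11 and -1.19), the lactate exporter Slc16a3 (-1.31 and -1.58) and Pdk1 (-1.03 and -1.04), which restrains pyruvate oxidation, were lower, while Ldhb (0.82 and 0.85) and the transporter Slc2a3 (0.50 and 0.57) were higher. Id1 (-1.18 and -1.21), Id2 (-1.66 and -1.51) and Id3 (-1.28 and -1.09), targets of BMP signalling, and Lefty1, a target of Nodal (-3.85 and -2.74), were lower in replicate 2. Eif4a3 was slightly lower in replicate 2 (-0.26 and -0.13).

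Across 12643 coding genes, which are not independent replicates, the ratio went with the coding share of the exons (Pearson's r = 0.252, Spearman's rho = 0.288).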
